A study of Aeromonas veronii with 3 samples.

How the data were processed

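The mRNA-seq libraries had been made from mRNA-enriched RNA with an Illumina kit, leaving out its poly-T step, per the labels' protocols. The groups were taken from the labels: leech crop fluid at 42 h, given as 2 sequencing runs, and LB mid-log culture, given as 1 library. The labels number the runs and do not say how many animals they came from. Both runs name the same pooled file, so each condition was treated as 1 sample and no p-value was computed. The aligner, the counting, the genome build and the annotation are not given in the sources used here.

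The authors deposited, for each library, a feature name, a coding length and an expression value that the file headers do not define. The deposited score is RPKM rounded to whole numbers, as found from the values: within rounding, each value times its coding length is a whole multiple of 1 step, and the library total that this step implies equals the sum of the whole reads it gives. Recovered reads reproduced 4202 of 4202 crop values and 4202 of 4202 LB values within 0.5, the rounding error. In simulated libraries treated the same way, reads were recovered exactly for 4202 of 4202 features in both. A read in a feature of 1 kb is worth 31.5 RPKM in the crop and 6.35 in LB. The crop file pools both runs, so agreement between them could not be measured. Of the 4202 lengths 4201 are multiples of 3, so they hold no UTRs, and 1748 features carry coordinates in their names. No rRNA or tRNA gene is among the features, and 632 features had 0 reads in both libraries.

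The design fixed before the data were examined had a branch for counts (TMM, 20 or more counts, interval excluding 1) and one for normalised values (ratio of values plus 1, no interval). As the deposited values are normalised, the second was used, with the 20-read minimum of the first applied to recovered reads. The branch for counts was run on recovered reads as an added alternative and its counts of genes stand beside the main ones. For lists the counts with the TMM factor alone are given. A gene was called at a fold of 2 or more. TMM trimmed 30% of log ratios and 5% of mean levels from each end. Counting intervals at 95% are exact conditional (Clopper-Pearson) intervals of the read ratio or, for a share, Clopper-Pearson binomial intervals. Folds against 0 reads are bounds from a floor of 3 reads in that library. A simulation with known changes set the 4 features that dominate the crop to a median level. It raised as many genes as it lowered, left the rest unchanged and drew reads with counting error only. There the deposited scale called 38.9% of 1046 unchanged genes, whose median log2 fold was -0.85, and the TMM scale with the interval called 1.63%. The latter recovered 85.4% of 48 genes raised 4-fold, 100% of 50 raised 16-fold, 32.6% of 46 lowered to 0.25 and 50% of 46 lowered to 0.0625. The data need not share these settings, so the percentages are not error rates for the 2 libraries.

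Of 37 gene lists fixed beforehand and matched by product name, as the features carry no symbols, 32 had 3 or more kept genes. A list's value is its median log2 fold minus that of all kept genes, with a percentile among 10000 random lists of the same size drawn from 10 strata of mean deposited value and an interval from 1000 gamma resamplings of the reads. In the simulation a list of 9 kept genes raised 4-fold lay at percentile 99.95 and one of 9 unchanged genes at 71.1. The pattern for amino-acid biosynthesis matched 0 features. That for mixed acid fermentation also matched dehydrogenases of other pathways (140 features, 7 of 41 kept genes higher and 15 lower, 17 and 11 with TMM, percentile 99.3), so it is not described as a pathway. A further 10 lists, corrected or new, were written after the names and the values had been seen. Patterns act on names, so some lists share genes or hold genes of other functions, and 12 lists were also taken without such members, 2 of which then had fewer than 3 kept genes. Named genes were, per direction, up to 15 with a named product and 100 or more reads, ranked by the interval bound nearest 1; the 10 most abundant protein-coding transcripts of each library; and in each list the 2 furthest up and 2 furthest down with 50 or more reads. Some of the genes that the rule names within lists are not printed.

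Alternatives were median-of-ratios factors, recovered reads scaled to their total with 0.5 read added, no read minimum, 100 reads, pseudocounts of 0.1 and 10, a fold of 4, LB thinned to the crop depth, lists matched on length and reads per kilobase. Added after the data were seen were the TMM variants, totals without the 4 dominant RNAs, the interval requirement, a minimum mean value of 100 and the lists without members of other functions. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.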

Results

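RNA of Aeromonas veronii, a bacterial symbiont of the medicinal leech, was sequenced from the intraluminal fluid of the leech crop, the part of the gut that stores the blood meal, and from mid-log cells grown in LB, a rich laboratory broth. The crop group held 2 sequencing runs at 42 h, which the deposited values pool into 1 set treated as 1 library, and the LB group held 1 library. Each library had a value for the same 4202 annotated features. The values were RPKM (reads per kilobase of coding length, scaled to the total reads of all features) rounded to whole numbers. The whole reads behind them could be recovered for every feature and came to 31726 reads in the crop and 157409 in LB, so LB was 4.96 times deeper in these reads. The totals count only reads assigned to the features. Reads of rRNA, tRNA or any other source are not seen, so sequencing depth is unknown, and shares below are of assigned reads. In the crop, 1820 features had 0 reads and only 299 had 10 or more, while in LB 929 had 0 and 1325 had 10 or more. With 1 such library per condition there was no replicate spread and no test. Folds below describe these libraries, their 95% intervals are exact conditional (Clopper-Pearson) ones, and intervals and floors cover counting error only. A library with 0 reads was set to a floor of 3 reads, which is 0.00946% of the crop reads and 0.00191% of the LB reads. Folds given as "at least" are taken against that floor and leave out the counting error of the other library's reads, so the exact 95% limits lie somewhat nearer to 1. In the lists below, a second pair of numbers marked TMM gives the genes higher and lower with that factor.

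A few features of short coding or RNA length dominated the reads assigned in the crop library. CsrB and CsrC, small regulatory RNAs that bind and sequester the translational regulator CsrA, held 30.4% (interval 29.9 to 30.9) and 10.1% (9.82 to 10.5) of the crop reads, against 0.463% and 0.203% of the LB reads. A hypothetical protein gene of 216 bases at 4362657 to 4362873 held 8.11% (7.82 to 8.42) of the crop reads and had 2 reads in LB. Another, of 324 bases at 3153645 to 3153969, held 2.47% (2.31 to 2.65) and had 1 read in LB. Together these 4 features took 51.1% (50.6 to 51.7) of the crop reads and 0.668% (0.628 to 0.709) of the LB reads. In LB the leading transcripts were a hypothetical protein gene at 533787 to 535167 (4.01%, 3.92 to 4.11), translation elongation factor G (3.11%, 3.03 to 3.20), a hypothetical protein gene at 4407130 to 4408111 (2.88%, 2.79 to 2.96) and ribosomal protein S1 (2.65%, 2.57 to 2.73). Next came the translocase subunit SecY, the alpha, beta' and beta subunits of RNA polymerase, ribosomal protein L2 and pyruvate dehydrogenase E1, from 2.47% down to 1.35%. The gene at 533787 was also abundant in the crop, at 3.44% (3.24 to 3.64), as were ribosomal protein S1 at 1.06%, the major outer membrane lipoprotein at 0.514% and a hypothetical protein gene at 20982 to 21609 at 0.485%. The 10 leading features held 57.6% of the crop reads and 22.5% of the LB reads. Counted per kilobase, the 10 leading features held 71.2% and 16.1%. Coordinates are those in the feature names, on a sequence called Aeromonas whose build is not given in the sources used here. The end minus the start equals the coding length, so 1 of the 2 end bases is not counted.

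The series set bacteria in the animal against bacteria in culture. Of 957 genes with 20 or more reads over both libraries, 121 were at least 2-fold higher and 585 at least 2-fold lower in the crop on the deposited scale, with 1 added to each value. When the counting interval also had to exclude 1, 105 were higher and 441 lower on this scale. Each of the 124 kept genes with 0 crop reads was called lower, also with the TMM factor alone. The added 1 stood in for their crop value, so the read minimum fixed these calls. The balance depended on the scale and on the genes admitted. The read minimum sums over libraries of unlike depth, so genes entered mostly through LB, with medians of 40 LB and 4 crop reads. A gene with few LB reads was kept only when its crop reads were many, which fixed its call as higher. With a minimum mean deposited value of 100 instead, added after the data were seen, 347 of 1108 genes were higher and 476 lower. The median log2 fold over the 957 genes was -1.58. It was -0.35 with a TMM factor over these genes, which by its construction sets the bulk of them nearly level and multiplies every fold, crop over LB, by 2.34. With the TMM factor 244 genes were higher and 345 lower, so that 41.4% of the calls were higher in place of 17.1%. With median-of-ratios factors the numbers were 251 and 331, without the 4 dominant RNAs 209 and 399, and with a TMM factor over all genes, which moved the median the other way to -1.82, 105 and 641. When the TMM factor was used and the counting interval also had to exclude 1, 195 genes were higher and 149 lower. All 121 genes called higher on the deposited scale were among the 195, and the 149 were all among the 585. As the factor multiplies every fold by 2.34, this nesting was largely set by construction. The folds that follow are on the deposited scale without a pseudocount. A fold higher in the crop is therefore larger by 2.34 times on the TMM scale, and a fold lower is smaller by as much.

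Among genes with a named product and 100 or more reads, CsrB was 65.6-fold higher (60.8 to 70.8; 9638 reads in the crop and 729 in LB) and CsrC 50.1-fold higher (44.6 to 56.4; 3220 and 319 reads). Phosphoenolpyruvate carboxykinase, the first committed enzyme of gluconeogenesis, was 10.5-fold higher (6.83 to 16.6; 68 and 32 reads). UDP-glucose dehydrogenase, at 1519893 to 1521261, was 8.27-fold higher (6.20 to 11.1), and ArnT, which adds aminoarabinose to lipid A and is encoded next to it at 1518224 to 1519868, was 3.35-fold higher (2.28 to 4.91). The sigma factors RpoH, of the heat-shock response, and RpoE, of the envelope stress response, were 7.32-fold (4.87 to 11.1) and 7.24-fold (4.99 to 10.6) higher. Translation initiation factor 3 was 2.51-fold higher (1.95 to 3.21) and a protease-related protein 2.58-fold higher (1.70 to 3.87). LpxC, the deacetylase that commits to lipid A synthesis, reached 1.82-fold (1.32 to 2.48). These 10 genes were all that had an interval above 1 at this read number. A second ArnT copy at 1526701, picked after its value was seen, had 11 crop and 94 LB reads. It was 0.581 times the LB level (0.280 to 1.09), or 1.36 times with TMM.

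The genes furthest below LB included several with no crop read at all. ImpC, a sheath protein of the type VI secretion system, had 0 crop reads against 571 in LB (0 and 2448 RPKM), at least 38.4-fold lower, and ImpB had 0 against 200, at least 13.4-fold lower. The hemolysin co-regulated proteins, which form the inner tube of the same system, had 0 against 291 reads at 2071373 to 2071721 and 0 against 279 at 4656572 to 4656824, at least 19.6-fold and 18.7-fold lower. A ClpB protein at 894350 to 896993 was at least 12.5-fold lower, with 0 against 186 reads. FlaA flagellin genes at 4635806 to 4636670 and 4634746 to 4635610 had 0 against 338 and 239 reads, at least 22.7-fold and 16.1-fold lower. Outer membrane proteins at 1366633 to 1367260 and 3955138 to 3955981 had 0 against 354 and 223 reads, the former at least 23.8-fold lower, and one at 2658917 to 2659955 was 22.2-fold lower (11.7 to 48.7; 9 and 992 reads). Biotin carboxylase, of fatty acid synthesis, had 1 crop read against 303 and was 61.1-fold lower (10.9 to 2420). All of these folds stayed above 4 on the TMM scale.

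Central carbon metabolism was described by branch, and the branches were not tested against each other. The pyruvate dehydrogenase complex, which makes acetyl-CoA from pyruvate, was lower in all its subunits. E1 was 12.6-fold lower (8.99 to 18.3; 34 and 2127 reads), the E2 acetyltransferase 16.6-fold (9.46 to 32.2) and lipoamide dehydrogenase 18.6-fold (9.74 to 40.8). In the list for acetate and glyoxylate metabolism, 1 of 4 kept genes was higher and 3 were lower. Phosphate acetyltransferase and acetate kinase (the copy at 3356973), which release acetate from acetyl-CoA, were 20.8-fold (8.87 to 64.5) and 9.70-fold (4.66 to 24.3) lower, while isocitrate lyase, the entry enzyme of the glyoxylate bypass, was 174-fold higher (29.2 to 7052; 35 reads and 1 read). Isocitrate lyase was kept only through its crop reads, so the read minimum fixed the 1 higher call of the list. That list's median lay 1.54 below the median of all genes on the log2 scale and its mean 0.83 above. With no read minimum, which admitted 10 genes, the median lay 4.66 above, at percentile 99.9 in place of 3.96, so the direction of the list depended on the genes admitted. Among those added, Malate synthase had 7 crop reads and 1 LB read, and Acetyl-coenzyme A synthetase 9 and 1. Of 16 kept genes of the TCA cycle, 4 were higher, 2 lower and 10 neither. Their median lay 1.72 (1.16 to 2.03) above that of all genes, at percentile 97.6 of 10000 random lists matched on mean expression. With the TMM factor 10 of the 16 were higher and 0 lower. The percentile depended on the genes admitted, at 78.4 with no read minimum and 71.5 with a minimum mean value of 100. Citrate synthase was 2.35-fold higher (1.26 to 4.22) and the succinate dehydrogenase iron-sulfur protein at 3474202 was 3.48-fold higher (2.16 to 5.55). The beta chain of succinyl-CoA ligase was 3.70-fold lower (1.20 to 18.5). Of 12 kept genes of glycolysis 0 were higher and 8 lower, among them the 2,3-bisphosphoglycerate-independent phosphoglycerate mutase, 13.5-fold lower (3.67 to 113), and the median lay 0.14 above that of all genes (percentile 48.5). It turned to 0.86 below with no read minimum (percentile 12.3) and to 1.16 below with a minimum mean value of 100 (24.1), so no direction is claimed. With the TMM factor 2 of the 12 were higher and 3 lower.

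Genes for taking up haem and iron were higher in the crop, the site of stored blood. Of 31 matched genes 8 had enough reads, of which 6 were higher and 0 lower (TMM 7 and 0), and their median lay 4.51 (3.75 to 5.08) above that of all genes on the log2 scale, at percentile 99.99. The 31 genes held 209 crop reads and 170 LB reads, a share 6.10-fold higher (4.96 to 7.51). Ferrous iron transport protein B was 193-fold higher (32.7 to 7836; 39 reads and 1 read), the outer-membrane heme receptor 38.0-fold (11.5 to 198; 23 and 3 reads), and a TPR domain protein of the TonB system, which energises such receptors, 24.1-fold (10.5 to 64.4). Each of these had 7 or fewer LB reads and was kept only through its crop reads, so the read minimum fixed their calls. With no read minimum, which admitted 25 genes, the list's median lay 4.61 above that of all genes (percentile 100). TolB, matched only because its product name mentions tonB, had 11 crop and 78 LB reads and was called neither way. Without it the share was 10.7-fold higher (8.30 to 13.8; 198 and 92 reads) and the median lay 6.06 above that of all genes. Genes named with fewer than 50 reads over both libraries, such as isocitrate lyase and these transporters, were picked after their values were seen. Haem synthesis had 0 of 6 kept genes higher and 4 lower (TMM 1 and 4; median 0.88 below all genes, percentile 26.2), including glutamate-1-semialdehyde aminotransferase, 11.5-fold lower (1.98 to 462). Iron storage and iron-sulfur assembly had 1 of 4 higher and 0 lower (TMM 2 and 0; percentile 75.4).

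In the stationary phase and starvation list 3 of 5 kept genes were higher and 1 was lower (TMM 3 and 1), with a median 4.08 (2.88 to 4.98) above that of all genes, at percentile 98.95. Ribosome modulation factor, which pairs idle ribosomes into inactive dimers, was 392-fold higher (68.3 to 15675; 79 reads and 1 read). The stationary-phase sigma factor RpoS was 39.7-fold higher (12.1 to 206; 24 and 3 reads). Ribosome modulation factor and RpoS were kept only through their crop reads, so the read minimum fixed their calls as higher. Ribosome hibernation protein YhbH was 5.67-fold higher (2.59 to 12.5; 16 and 14 reads). Stringent starvation protein B had 0 against 29 reads, at least 1.95-fold lower, and that bound did not reach 1 on the TMM scale. Its call as lower was fixed by its 0 crop reads. The list for phage and mobile elements had 4 of 5 kept genes higher and 0 lower (TMM 5 and 0; median 8.17 above all genes, percentile 99.95), but the leading members were not phage genes. They were phage shock proteins, which respond to damage of the inner membrane. PspA at 769007 to 769670 had 93 crop reads and 0 in LB, at least 154-fold higher, and PspA at 1241368 to 1242055 had 72 and 0, at least 119-fold higher. In the amino-acid catabolism list 2 of 7 kept genes were higher and 2 lower (TMM 2 and 1; median 1.09 above all genes, percentile 87.1). Arginine deiminase, which opens the pathway that makes ATP from arginine, had 96 crop reads and 0 in LB, at least 159-fold higher. Like the PspA genes, arginine deiminase was kept only through its crop reads, so the read minimum fixed its call. L-serine dehydratase was 3.91-fold lower (1.62 to 12.3). CsrB is 469 bases long. With the 4 dominant features and the ribosomal list left out, kept genes of that length or shorter had a median log2 fold of -0.41, and longer ones -1.59. Ribosome modulation factor, at 180 bases, is one of the short ones.

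Transcripts for making protein took a smaller part of the crop library. The 61 genes matched as ribosomal proteins, 5 of them modifying enzymes with 8 crop reads together, held 6.78% (6.50 to 7.06) of the crop reads and 28.3% (28.1 to 28.5) of the LB reads. Of 57 kept, 0 were higher and 49 lower, and with the TMM factor 1 was higher and 28 lower. Their median lay 0.64 (0.52 to 0.86) below that of all genes, at percentile 16.3 of lists of like expression. It was at percentile 0 of lists matched on length and at 0.02 with no read minimum, but only 0.02 below all genes at 100 reads (percentile 25.5) and at percentile 26.7 with LB thinned to the crop depth. Its place thus depended on what it was set against. L7/L12 was 10.9-fold lower (6.34 to 20.6) and S1 2.49-fold lower (2.23 to 2.80), while L35 was 1.36-fold higher (0.899 to 2.02). The list for translation factors had 2 of 12 kept genes higher and 10 lower (TMM 2 and 5; percentile 25.8, or 43.3 without the transcription factor GreA that its pattern matched), with elongation factors G and Ts 9.59-fold (7.89 to 11.8) and 9.72-fold (6.19 to 16.2) lower. Its median, 0.38 below that of all genes, turned to 0.12 above at 100 reads (percentile 56.1) and 0.01 above with LB thinned (54.3). The ATP synthase list lay lower still. All 9 kept genes, 1 of them the flagellar FliI, were lower, 7 of them also with the TMM factor, and the median lay 1.16 (0.73 to 1.61) below that of all genes, at percentile 2.06 (4.78 against lists matched on length). Aerobic respiration had 0 of 15 higher and 9 lower (TMM 2 and 6; percentile 8.38), including the sodium-pumping NADH-quinone reductase subunit B, 12.5-fold lower (6.01 to 31.3). Cell division and DNA replication had 1 of 17 higher, the rRNA methyltransferase FtsJ, and 14 lower (TMM 3 and 6; percentile 31.3), with 1 crop read against 180 for DNA gyrase subunit B, 36.3-fold lower (6.43 to 1441). Purine and pyrimidine biosynthesis had 0 of 5 higher and 4 lower (TMM 1 and 2; percentile 39.2), with GMP synthase at 0 against 63 reads, at least 4.23-fold lower.

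Lists for motility and secretion were described singly and not tested against one another. Of 98 genes matched as flagella, 29 were kept, of which 0 were higher and 24 lower, with 93 crop reads against 2094 in all, a share 4.54-fold lower (3.69 to 5.65). With the TMM factor 1 was higher and 15 lower. Both counts of lower genes include the 9 kept genes with 0 crop reads, whose calls were fixed by the 1 added to each value. The median of the 29 genes lay 0.68 below that of all genes (percentile 9.24). It lay 0.10 below with the 0-read genes, 9 of the 29, set to the floor of 3 reads. That floor puts them above genes with 1 or 2 crop reads, so this value sets no limit on the difference. Of the 98 genes, 9 were type III secretion genes with 2 crop and 17 LB reads, none of them kept, and the kept CheY belongs to chemotaxis. Chemotaxis had 2 of 10 kept genes higher and 6 lower (TMM 3 and 2; percentile 62.0). All 55 matched chemotaxis genes together held a share 1.53-fold higher (1.27 to 1.83), and with no read minimum the list lay at percentile 99.6. The pattern fixed for type VI secretion matched 7 genes, of which 3 were kept. All 7 had 0 crop reads, against 187 LB reads together, at least 12.6-fold lower, and the median lay 5.75 below that of all genes (percentile 1.48). With 0-read genes at the same floor the median lay 0.25 below, which likewise sets no limit. Type III secretion, the injection apparatus for effector proteins, was sparse in both libraries. Its 40 genes had 49 crop and 143 LB reads, a share 1.70-fold higher (1.20 to 2.37), and the 1 kept gene, YopD, was 7.67-fold higher (3.39 to 18.1; 17 and 11 reads). With 11 LB reads YopD passed the minimum of 20 only through its crop reads, so its call was fixed. The share of the 40 genes rested on YopD and YopB, with 29 of the 49 crop reads. The other 38 genes had 20 crop and 126 LB reads, 0.788 times the LB share (0.465 to 1.27), which the TMM factor would raise above 1. Type II secretion had 1 of 4 higher and 1 lower (TMM 3 and 0; percentile 95.2), but lay below all genes at percentile 1.47 with no read minimum. Type IV pili and fimbriae had 2 of 5 higher and 2 lower (TMM 2 and 2; percentile 88.1), and their share was 1.77-fold higher (1.38 to 2.27). Toxins and secreted hydrolases had 2 of 9 higher and 7 lower (TMM 2 and 4; percentile 40.5), where the most negative members were the 2 hemolysin co-regulated proteins of type VI secretion. The list for outer-membrane porins, whose pattern matched outer-membrane proteins in general, had 2 of 15 higher and 9 lower (TMM 2 and 6; percentile 6.01). Of the 9, 4 were not porins: the assembly factors YaeT, NlpB and YfgL, and ImpK/VasF of type VI secretion. Left with 7 genes after 8 such members were taken out, a choice made after the values were seen, the list had 2 higher and 5 lower (TMM 2 and 4) and lay at percentile 0.555. An OmpA precursor at 306381 to 307380 was 6.04-fold higher (3.36 to 11.0). Its neighbour at 305054 to 306074, picked after its value was seen, was 10.2-fold lower (5.65 to 20.5). Strand is not given in the sources used here, so reads of antisense or overlapping transcripts were not separated. Without sequence, reads shared between similar copies, as of FlaA or ArnT, could not be checked.

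The remaining lists lay outside the 2.5% at either end of the matched lists. Chaperones and heat-shock proteases had 1 of 13 higher and 11 lower (TMM 1 and 5; percentile 18.2), with DnaK 5.16-fold lower (2.91 to 10.1) and the protease subunit ClpA 4.30-fold higher (2.73 to 6.75). Oxidative stress defence had 0 of 10 higher and 6 lower (TMM 2 and 5; percentile 41.8), with Tpx-type thiol peroxidase 27.6-fold lower (4.87 to 1098) and iron superoxide dismutase 5.90-fold lower (2.94 to 13.8). Cold shock genes split, 2 of 4 higher and 2 lower (TMM 2 and 0; percentile 88.0): CspG was 2.95-fold higher (1.58 to 5.36), whereas CspE at 2576503 was 2.16-fold lower (1.51 to 3.18) on the deposited scale and slightly higher with TMM and median-of-ratios factors. Osmotic adaptation had 0 of 7 higher and 7 lower (TMM 0 and 3; percentile 43.8), and phosphate uptake 0 of 4 higher and 3 lower (TMM 0 and 2; percentile 34.0, median below and mean level with that of all genes; 50.4 without a glycerol-3-phosphate transporter). With every 0-read gene set to the floor, glycolysis and chemotaxis moved from slightly above to 0.19 and 0.22 below all genes, and oxidative stress defence from 0.12 below to 0.26 above. As the floor of 3 reads puts such genes above those with 1 or 2 reads, these moves do not bound the medians. Other lists also changed side with the genes admitted. At 100 reads the medians of chaperones, cell division and oxidative stress defence turned from below to 0.28, 0.13 and 0.48 above that of all genes. With no read minimum toxins, phosphate uptake, purine and pyrimidine biosynthesis, haem synthesis and osmotic adaptation turned to 0.83, 2.13, 0.45, 0.31 and 0.01 above, and sugar use to slightly below. At a minimum mean value of 100 chemotaxis turned to 1.06 below. Sugar phosphotransferase and glycan use had 4 of 23 higher and 12 lower on the deposited scale, but 9 and 8 with TMM (percentile 71.5), with the trehalose transporter 13.9-fold lower (2.41 to 557). Its pattern also matched LpxC and 7 other kept genes of envelope, nucleotide or RNA metabolism, without which 3 of 15 were higher and 8 lower (TMM 6 and 5; percentile 67.2). Glycerol and fatty-acid use had 4 of 9 higher and 4 lower (TMM 4 and 3; percentile 86.1), with an acyl-CoA dehydrogenase 28.5-fold higher (13.3 to 70.0) and a long-chain fatty acid transport protein 12.1-fold lower (4.68 to 44.9). The acyl-CoA dehydrogenase, with 46 crop and 8 LB reads, was kept only through its crop reads, so its call was fixed. Nitrogen assimilation had 0 of 3 higher and 1 lower, a folate synthase that its pattern matched (TMM 2 and 1; percentile 95.8, median above and mean below that of all genes), and anaerobic respiration 1 of 3 higher and 1 lower (TMM 2 and 1; percentile 89.6). Quorum sensing had 21 crop and 72 LB reads, zinc and manganese uptake 15 and 13, and the SOS response 10 and 65, with fewer than 3 kept genes each.

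**Figure D1:**
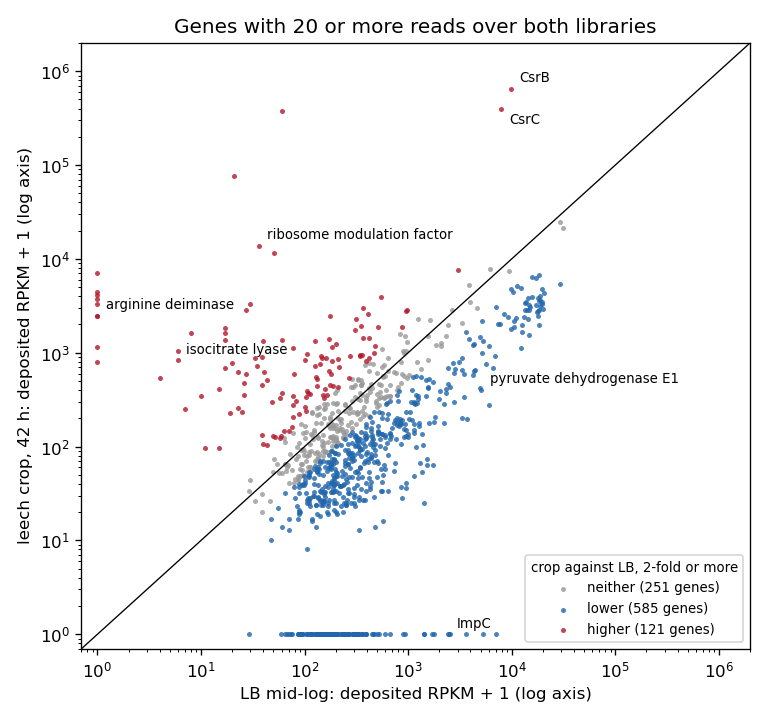
Deposited RPKM plus 1 of the 957 kept genes in LB (horizontal, log axis) and in the crop (vertical, log axis), 1 point per gene, coloured by a difference of 2-fold or more on the deposited scale. CsrB and CsrC lie far above the line of equal values, and 124 genes with 0 crop reads lie along the bottom.

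**Figure D2:**
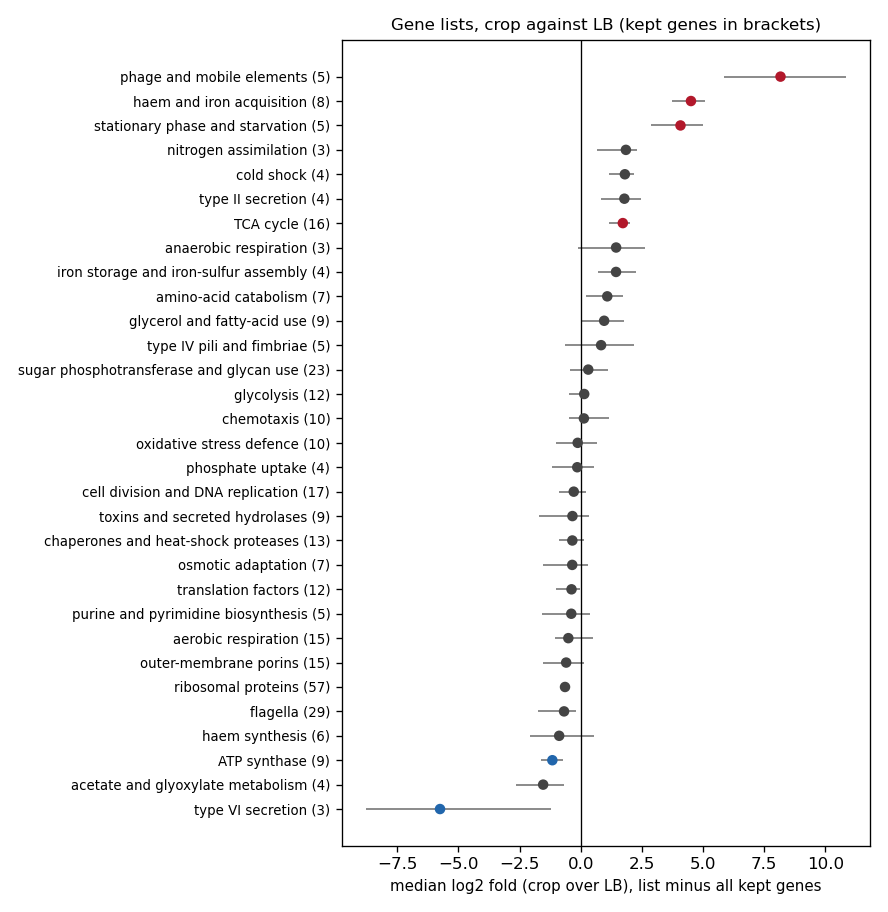
Median log2 fold (crop over LB) of each gene list minus that of all kept genes, with the number of kept genes in brackets and lines for the 95% interval from 1000 resamplings of the read counts. Red points lie in the highest 2.5% of matched random lists and blue points in the lowest 2.5%. The mixed acid fermentation list, whose pattern matched unrelated dehydrogenases, is left out.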

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

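The TMM settings, the totals without the 4 dominant RNAs, the interval requirement, the minimum mean value, the thinned lists and the lists without members of other functions were chosen after seeing the data. Where not stated, the cause was not tested. The counts of genes at least 2-fold higher (121) or lower (585) depended on scale and on the read minimum. Higher and lower genes numbered 251 and 331 with median-of-ratios factors, 244 and 345 with TMM, and 195 and 149 with TMM plus the interval, while 209 were higher without the 4 RNAs. With the interval on the deposited scale, 105 were higher and 441 lower. Higher and lower genes were 1091 and 1761 of 3570 with no read minimum, 12 and 193 of 243 at 100 reads, and 77 and 231 of 378 with LB thinned to the crop depth, where a different number of genes entered. At a fold of 4, 74 were higher and 406 lower, by construction, and at a mean value of 100 or more, 347 and 476. Pseudocounts of 0.1 and 10 gave 121 and 117 higher, 585 and 568 lower. Of 32 lists 5 lay in the highest 2.5% (haem and iron, stationary phase, phage, TCA cycle and the too broad mixed acid list) and 2 in the lowest. A factor per library cancels out of these values, so scale factors could not change them; pseudocounts in RPKM kept the same lists, and 0.5 read added gave 4 and 2. With no read minimum these were 8 and 6. Acetate and glyoxylate (percentile 99.9, from 3.96), chemotaxis (99.6), amino-acid catabolism (99.5) and glycerol and fatty-acid use (99.1) entered the highest. Ribosomal proteins (0.02), type II secretion (1.47, from 95.2), flagella and cell division (0.86) entered the lowest. Ribosomal proteins also did so at percentile 0 when matched on length, but lay at 25.5 at 100 reads and 26.7 with LB thinned. Glycolysis turned from above all genes to below with no minimum (12.3), at a mean value of 100 (24.1) and with LB thinned (36.4), and translation factors from below to above at 100 reads (56.1) and with LB thinned (54.3). Haem and iron rose from 4.51 to 6.06 without TolB. Without members of other functions 4 of 30 lists lay in the highest, as the phage list was no longer scored, and 3 in the lowest, which porins entered (0.555, from 6.01). At 100 reads 1 of 13 lists lay in the highest, and it was not among the 5. The haem and iron, stationary phase and phage lists stayed in the highest 2.5% in every setting that scored them. The TCA cycle left it at percentile 97.4 with recovered reads plus 0.5, 78.4 with no read minimum and 71.5 at a mean value of 100 or more. The ATP synthase list left the lowest 2.5% at percentile 12.6 at 100 reads and 4.78 when matched on length. Flagella, at percentile 9.24, lay at 0.3 or lower at 100 reads, with LB thinned, with no minimum and at a mean value of 100. The 10 leading features held 71.2% of crop and 16.1% of LB reads per kilobase, against 57.6% and 22.5% of reads. Of 96 named genes 7 changed sign with median-of-ratios or TMM. Only CspE among them was called (lower), with log2 folds of 0.17 with median-of-ratios, 0.12 with TMM and 0.14 with TMM plus the interval. Not run were leaving out a crop run (the runs are pooled) and symbol matching (no symbols). Totals over all features and the authors' own values equal the main analysis by construction. Depth limits the crop most: its median was 4 reads per kept gene, against 40 in LB.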

Other observations

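The lists in this part and all tests but those of short transcripts and of depth on ribosomal shares were written after the values had been seen. The arginine deiminase pathway converts arginine to ornithine with a gain of ATP. Of its 9 matched genes 4 were kept, and all 4 were called higher. Each had 0 or 1 LB read and was kept only through its crop reads, so the read minimum fixed these calls. All 9 genes together had 233 crop and 33 LB reads, a share 35.0-fold higher (24.3 to 52.1). ArcD at 1705273 to 1706680 had 46 crop reads and 1 LB read (228-fold higher, 39.0 to 9208), its neighbour ornithine carbamoyltransferase at 1706803 to 1707808 had 37 and 0 (at least 61.2-fold higher), and carbamate kinase had 48 and 1 (238-fold, 40.7 to 9600). Other ArcD copies at 225683 and 3723634 had 0 crop reads, against 17 and 11 in LB. Phage shock proteins B and C had 12 and 21 crop reads against 1 LB read each. Of 4 kept genes for RpoE, its regulators and RpoH, 3 were higher and 0 lower (TMM 4 and 0). The anti-sigma factor RseA was 6.36-fold higher (4.10 to 9.93). RseB, at 1.93-fold (0.681 to 4.84), was called neither way, and RseC, with 3 crop and 7 LB reads, was not kept. CspD, a stationary-phase relative of the cold shock proteins, had 29 crop reads and 0 in LB, at least 48.0-fold higher. UvrY, the response regulator that drives CsrB and CsrC in related bacteria, was 3.31-fold higher (1.45 to 7.26). The BarA sensor kinase had 2 crop and 11 LB reads, 0.902 times the LB level (0.0972 to 4.13). CsrA, the target of CsrB and CsrC, had 2 crop and 14 LB reads, 0.709 times the LB level (0.0782 to 3.09). With TMM these were 2.11 and 1.66 times, so no direction is claimed for BarA or CsrA.

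Of 22 kept aminoacyl-tRNA synthetases 0 were higher and 21 lower, 14 of them also with the TMM factor, and their median lay 1.02 (0.68 to 1.53) below that of all genes, at percentile 0.14. The fermentation list without other dehydrogenases had 1 of 5 kept genes higher and 2 lower (2 and 1 with TMM; percentile 70.4). Of 5 kept aminoarabinose genes, ArnT at 1518224 was higher and 2 were lower on the deposited scale, but 2 were higher and 0 lower with TMM (percentile 61.4). A hypothetical protein gene at 3335373 to 3335829 had 102 crop reads and 0 in LB, at least 169-fold higher, and PhaF had 45 and 0, at least 74.4-fold higher.

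The 4 features that took 51.1% of the crop reads were all 469 bases or shorter. Preferential keeping of short transcripts may have added to this: 82 other kept genes of that length, outside the ribosomal list, had a median log2 fold 1.18 (0.40 to 1.94) above that of 814 longer genes. The interval spans the predicted difference of 1, so the test leaves this open. It also sorts genes by feature length, as transcript lengths are not given, and so cannot tell short transcripts from long ones. The read minimum acts on reads per feature, which depend on length, and its effect on the difference was not measured. A difference of that size is far below the log2 folds of these 4 features. Reads of another crop organism could be assigned to the 2 hypothetical protein genes, which had 3 LB reads together, but transcription only in the crop predicts the same, and these cannot be told apart without sequence. CsrB and CsrC had 729 and 319 reads in LB and so were transcribed in culture as well.

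The smaller share of ribosomal-protein reads in the crop was 0.239 times that in LB. The 4 dominant RNAs do not account for all of it, since without them the ratio was 0.486 (0.465 to 0.508). With LB thinned to the crop depth it was 0.237 (0.226 to 0.249), but thinning keeps expected shares, so this value decides nothing about depth. Slower growth in the crop than at mid-log is a candidate explanation, and the stationary phase and starvation list lay at percentile 98.95. The higher genes of that list passed the read minimum only through their crop reads, so this percentile decides nothing. Growth phase, host and medium differ together between the 2 libraries, so an effect of growth rate and one of the leech cannot be told apart.

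By all their product names, 19 type VI secretion features had 2055 LB reads and 0 crop reads, at least 138-fold lower, or 59.0-fold on the TMM scale. Depth is argued against: at an unchanged level the crop would have held at least 171 of their reads under any scaling tried. All 15 kept features had 0 crop reads, against 62 of 530 other genes with 30 to 571 LB reads. A crop strain that lacks these genes, or differs from the reference there, may explain it, and the most crop reads of any type VI feature was 0. Silent transcription predicts 0 as well, so absence and regulation cannot be told apart. Also at 0 crop reads were all 6 type I restriction-modification genes (174 LB reads), a protelomerase (48) and the replication protein RepA (56), while 5 flagellins had 2 crop reads and 759 in LB.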
